A study of Mus musculus with 6 samples.

How the data were processed

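5hmC immunoprecipitation libraries of sorted immature myeloid cells transduced with AML1-ETO were compared between Tet2 flox cells given ethanol (2 libraries) and Tet2 KO cells given 4-hydroxytamoxifen (2 libraries). Groups and replicate numbers came from the sample titles. Of the 6 samples of the series, the IgG control and the input were not used here. Per the labels, the 4 libraries were made with 14 PCR cycles and ran in lane 3. Whether they shared a flow cell or run is not given in the sources used here.

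The submitters' processing notes name CASAVA 1.8, Bowtie, MACS 1.4 and the mouse build GRCm38 (mm10), without roles or order. The settings, the control library of the peak calling and the treatment of duplicate reads are not given in the sources used here. Each deposited file was a list of peaks of 1 library, with start and end in bp. The deposited score of each peak was checked to be -10 times the log10 of the deposited p-value within 0.02, with 1 exception in 1 list, and the lowest score was 50. Both score and p-value are the authors' own values for the peak within its library. They were used only to describe, rank or filter peaks. Scores depend on depth, which was unknown, so intervals given with shares cover counting error over regions only. Each list holds the peaks of 1 library, and more depth can add weak peaks. In each list, 16 to 27 numbers of the caller's running peak number had no peak, and those were not analysed here.

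Called length was the number of bases under peaks. Regions were made by merging overlapping peaks (1 bp or more) of the 4 lists. Merging with bedtools 2.31.1 gave the same number of regions, and bedtools also counted the peaks shared between 2 libraries. A region was flox-only or KO-only when called in both libraries of that genotype and in neither of the other. Coordinates are on GRCm38 and counted from 1. Gene positions came from RefSeq spans of 21887 protein-coding genes on the same build. This table has no strand, exons or sequence. The planned interval, the gene body with 5 kb upstream, was therefore replaced by the gene body with 5 kb at both ends, and the transcription start by both gene ends. Exons, introns, CpG islands, promoters on their own and the exons of Tet2 were not analysed here. Extended this way, 9612 genes overlapped another gene and can share peaks with it. The genome's share in genes was taken from 3 Mb to the last gene or peak of each chromosome.

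Called length per gene was scaled to the same total in each library and tested as log2(bp + 500) with limma 3.58.1 (R 4.3.3, trend and robust) for genes with a mean of at least 500 bp, with Benjamini-Hochberg adjusted p under 0.05 as threshold. Differences on this scale understate the change of genes with little called length. The test was checked on simulated data (14162 genes, 100 genes at each of the log2 changes 1 and 3, falls and rises together). Their spread was smoothed over genes by mean called length, so simulated genes of equal mean shared the same spread. There the test made 9 false calls, and 1 call when nothing was changed. The 11 gene lists, the tests planned for each comparison and the rule for named genes were fixed before the data were examined. Other measures and tests were added later. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation), two-sided and adjusted over the 11 lists. Regions in list genes, places and distances were compared by two-sided Fisher's exact tests, and library values by two-sided exact permutation tests, for which 2 against 2 allows no p under 0.333. Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

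Named genes were the 12 genes per direction with the largest difference among those past the threshold, with both KO libraries on 1 side of both flox libraries and a mean of at least 2000 bp, leaving out symbols of Gm plus digits or ending in Rik. With fewer than 6 passing, the 6 with the smallest p were taken and said not to pass, which was the case in both directions. In each list, up to 2 genes with the largest excess of flox-only regions and 2 with the largest excess of KO-only regions were named, and the 5 widest regions of each genotype. Tet1, Tet2 and Tet3 were always named. Some genes that this rule names are not reported here. Alternatives were peaks with a score of at least 100, the 50000 highest scored peaks, leaving out the 10% lowest scored peaks, other overlap rules, pseudocounts, filters, intervals and scaling, a replicate block, and each library left out.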

Results

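The base 5-hydroxymethylcytosine (5hmC), which TET enzymes make by oxidising 5-methylcytosine, was mapped in the genome of mouse blood cells by immunoprecipitation of DNA fragments with an antibody to 5hmC, followed by sequencing. The cells came from bone marrow enriched for Kit, a receptor of blood stem and progenitor cells, and had been given AML1-ETO, the fusion protein of a recurrent translocation in acute myeloid leukaemia. They carried a Tet2 gene that Cre recombinase can excise and a Cre that responds to 4-hydroxytamoxifen. Cultures given 200 nM of this drug for 2 passages (4 days) are called KO here, and cultures given ethanol are called flox. Sorted immature myeloid cells at passage 5 were profiled in 2 libraries per group, and the comparison asks what loss of Tet2 does to the places where 5hmC is found. Only KO cultures were given the drug, so effects of the drug or of active Cre cannot be told apart from loss of Tet2. The authors' peak lists held 118727 and 118522 peaks in flox replicates 1 and 2, and 116539 and 122101 peaks in KO replicates 1 and 2. The number of reads behind each list was unknown. The labels do not say whether replicates were separate cultures, so the spread between these 4 libraries may be technical. Limma and the tests of library values measure differences against this spread. Tests on regions take regions as units, and camera with a preset correlation takes genes. Their p-values do not measure the spread between libraries. An IgG control and an input library were not used here.

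Tet2 itself, the gene targeted in the KO cells, carried 5hmC peaks in both groups. The gene (chromosome 3, 133463677 to 133545136, GRCm38) held 2 peaks in each flox library, 2 in KO replicate 1 and 3 in KO replicate 2. The region at 133512266 to 133513916 inside the gene was called in all 4 libraries, with peak scores of the authors' caller of 812 and 438 in flox and 445 and 419 in KO. Called length over Tet2 and 5 kb on either side averaged 2742 bp in flox and 2452 bp in KO (log2 difference -0.09, SE 0.31, limma adjusted p = 0.979). The labels do not name the excised part of the gene, so these peaks check nothing about the deletion. Tet1 (chromosome 10, 62804570 to 62887469), another 5-methylcytosine oxidase, had 3868 bp in flox and 2486 bp in KO (log2 difference -0.55, SE 0.20). Tet3 (chromosome 6, 83362373 to 83457208), the third enzyme of the family, had 6727 bp and 4638 bp (-0.51, SE 0.22, and -0.26 without KO replicate 2). Both KO libraries lay below both flox libraries at Tet1 and Tet3, and neither gene passed the test over all genes (limma adjusted p = 0.791 and 0.824). At Tet3, a region at 83367929 to 83368882 was called in both flox libraries and in neither KO library, and was singled out after its values were seen. No region inside Tet1 had this pattern. Those inside Tet1 that were not called in all 4 libraries were each called in 1 library alone, with scores of 50.28 to 105.75.

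The KO cells had about as many 5hmC peaks as the flox cells, and mostly in the same places. Between any 2 libraries, 74.79% to 75.99% of peaks overlapped. Flox libraries held 118625 ± 145 peaks covering 111.8 ± 2.16 Mb, and KO libraries held 119320 ± 3933 peaks covering 110.7 ± 0.59 Mb (SD, n = 2 each, two-sided exact permutation p = 1.0 for both). Of 174070 regions made by merging the 4 lists, 68764 (39.5%) were called in every library. Any pair of libraries shared 0.494 to 0.506 of their called bases (Jaccard index, shared over total called bases). The flox pair stood at 0.499, the KO pair at 0.506 and the 4 pairs across genotypes at 0.494 to 0.502. Median peak length was 902 and 879 bp in flox and 898 and 864 bp in KO. With 2 libraries against 2, no exact test can give a p below 0.333. Peaks were called within each library, so a change of the 5hmC level across the whole genome need not show in their number.

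Regions called in 1 genotype alone were about as frequent in flox as in KO cells, and they differed in where they lay. There were 5146 regions called in both flox libraries and in neither KO library (flox-only), and 5228 with the reverse pattern (KO-only), a ratio of 0.984. Flox-only regions lay inside protein-coding genes in 43.8% of cases (95% Wilson interval 42.43 to 45.14) and KO-only regions in 36.3% (35.01 to 37.62). Regions called in all 4 libraries stood between them at 40.6%, and 38.7% of the genome lies in such genes. Far from genes the order was the reverse, with 28.4% of flox-only and 35.9% of KO-only regions over 100 kb from the nearest gene end. The pooled share in genes was settled after a first look at the regions. The exclusive classes that follow stand in for planned classes by transcription start, exon and intron, which the gene table does not allow.

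The 5 widest flox-only regions included 1 in Tnk2 (chromosome 16, 32656140 to 32659758), a non-receptor tyrosine kinase gene, and 1 in Synj2 (chromosome 17, 5994242 to 5997791), which encodes a phosphoinositide phosphatase. A further region of this set lay in Klhl2 (chromosome 8, 64826193 to 64829273). The widest of all spanned 4219 bp at chromosome 17, 87952313 to 87956531, and was 18518 bp from the mismatch repair gene Msh6. The fifth lay 9657 bp from Coq2, a coenzyme Q synthesis gene, on chromosome 5 (100642101 to 100645065). Among the 5 widest KO-only regions, the first spanned 3049 bp inside Gse1 (chromosome 8, 120281602 to 120284650). Another lay in the sodium channel gene Scn10a (chromosome 9, 119650121 to 119652415). The other 3 lay between genes, nearest to Cd300a (chromosome 11, 114905848 to 114908296), Erc1 (chromosome 6, 119852446 to 119854789) and the homeobox gene Meis1 (chromosome 11, 18740303 to 18742624). Meis1, a stem cell and leukaemia regulator, was 137803 bp away. Each of these regions was called in both libraries of its genotype and in neither of the other. At some of them the width came mostly from 1 library, as in Synj2 (970 and 3550 bp called in flox replicates 1 and 2) and Klhl2 (3081 and 1641 bp). At the region near Msh6 the 2 libraries were close (4201 and 4143 bp).

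By exclusive class, gene bodies held 42.3% of flox-only and 34.8% of KO-only regions (odds ratio 1.367, 95% interval 1.263 to 1.48, Fisher's exact test, adjusted p = 1.595e-14). Regions within 1 kb of a gene end made up 3.05% and 2.96% (adjusted p = 0.818), and intergenic regions 54.7% and 62.2% (adjusted p = 1.595e-14). By distance to a gene end, 22.2% of flox-only and 16.8% of KO-only regions lay 1 to 10 kb away (odds ratio 1.413, adjusted p = 8.462e-12). At 10 to 100 kb the shares were 46.4% and 44.3% (adjusted p = 0.0465), and beyond 100 kb the odds ratio was 0.707 (adjusted p = 7.832e-16). The share in genes differed by 7.48 percentage points between the genotypes' own regions (odds ratio 1.366, Fisher's exact p = 8.497e-15). The same difference was 1.11 points (Fisher's exact p = 0.260) when the libraries were split by replicate number, and -2.09 points (exact p = 0.0377) when they were split crosswise. Regions called only in a pair of 1 flox and 1 KO library lay in genes in 36.76% to 38.97% of cases and over 100 kb from a gene end in 32.98% to 36.09%. Flox-only regions lay outside both ranges, while the interval of KO-only regions in genes (35.01 to 37.62%) reached into the first and their 35.9% over 100 kb lay within the second.

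**Figure D1:**
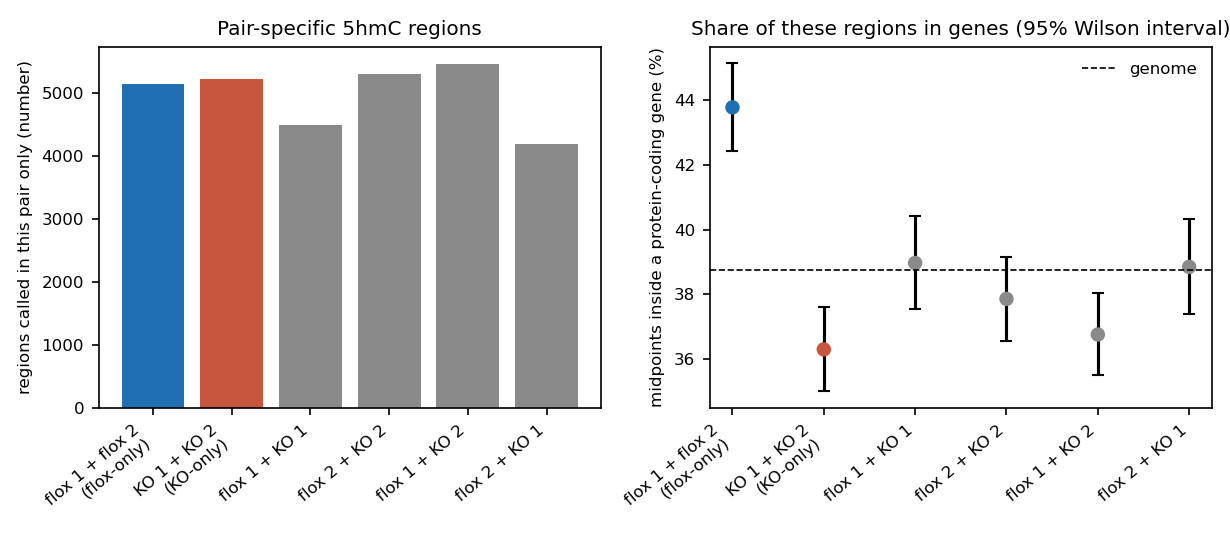
The left panel gives, for each pair of libraries, the number of regions called in both libraries of the pair and in neither of the others (bars). The right panel gives the percent of these regions whose midpoint lay in a protein-coding gene (points, with 95% Wilson intervals) and the genome's own share (dashed line). The 6 counts lie between 4185 and 5459, and the flox pair has the highest share in genes (43.8%) and the KO pair the lowest (36.3%).

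Over whole peak lists the same order was seen on a smaller scale. Peak midpoints lay in genes in 40.49% of cases in each flox library, 39.68% in KO replicate 1 and 39.27% in KO replicate 2, and more than 100 kb from any gene end in 29.6% ± 0.02 of flox and 30.7% ± 0.47 of KO peaks (SD, n = 2, exact permutation p = 0.333 for each, the smallest possible). Of called bases, 41.5% ± 0.04 in flox and 40.2% ± 0.30 in KO lay in genes. Regions of 1 genotype were mostly low-scored peaks. In flox replicates 1 and 2, 48.4% and 45.2% of flox-only peaks fell in the lowest score quartile of their own list, and 1.92% and 3.62% in the highest. For KO-only peaks these shares were 49.1% and 47.1% in the lowest and 1.20% and 2.02% in the highest quartile, while 39.5% to 40.7% of peaks in regions called in all 4 libraries were in the highest. The Fisher tests count regions of 4 libraries, not independent cultures. Other pairs of libraries had 4185 to 5459 regions of their own, a range that holds the counts of flox-only and of KO-only regions. Their sum was 10374, against 9797 in the split by replicate number and 9644 in the crossed split, and it was the highest of the 3 splits in all 7 settings in which the splits were compared. The mean Jaccard index was 0.502 within and 0.498 between genotypes.

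**Figure D2:**
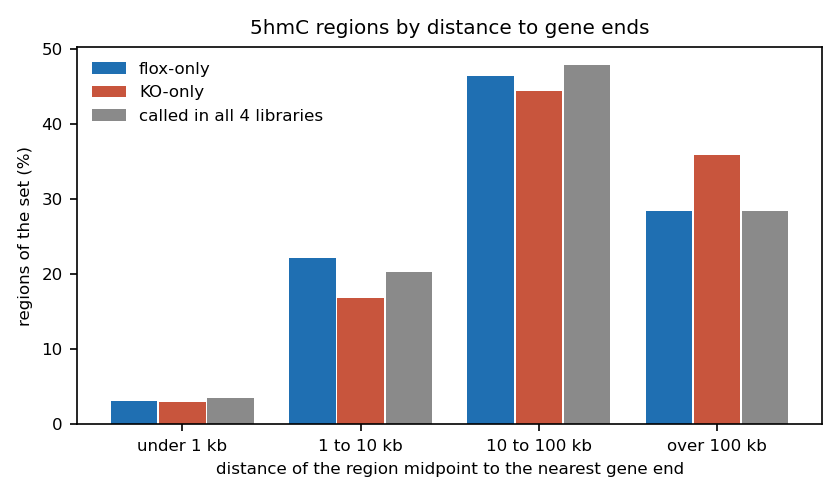
Bars give the percent of flox-only, KO-only and 4-library regions in each class of distance from the region's midpoint to the nearest end of a protein-coding gene. Between 1 and 10 kb flox-only regions take 22.2% and KO-only regions 16.8%, and over 100 kb the shares are 28.4% and 35.9%.

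No single gene passed the test for called 5hmC length, and the genes with the smallest p-values had mostly less of it in KO. Tiam1, which encodes an activator of the GTPase Rac1, had 28745 bp called in flox and 16165 bp in KO (chromosome 16, 89787111 to 90145600, log2 difference -0.81, SE 0.09). Cyba, a subunit of the NADPH oxidase of phagocytes, had 3788 bp and 374 bp (chromosome 8, 122424771 to 122432940, -2.33, SE 0.33). A flox-only region inside the neighbouring gene Mvd (122436087 to 122437734) lies in the 5 kb beside Cyba and counts toward this length. Also lower were the lipid transporter gene Abca2 (chromosome 2, log2 difference -1.69), the endosomal sorting gene Vps37b (chromosome 5, -1.55) and the myelin gene Mbp (chromosome 18, -0.58).

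Higher in KO were Vopp1, with 811 bp in flox and 3549 bp in KO (chromosome 6, 57752264 to 57827983, log2 difference 1.63, SE 0.25), and the potassium channel interactor gene Kcnip4, with 22502 bp and 32338 bp (chromosome 5, 48389503 to 49525122, 0.51, SE 0.10). The neural transcription factor gene Pou3f2 had 1282 bp and 3400 bp (chromosome 4, 1.13). Lmbrd1, which serves lysosomal cobalamin export, differed by 1.13 (chromosome 1), Gprin3 by 1.55 (chromosome 6) and Mccc2, a gene of leucine breakdown, by 0.84 (chromosome 13). For each of these 11 genes both KO libraries lay on the same side of both flox libraries, and the limma adjusted p was 0.773 for all 11. The order of Abca2, Kcnip4 and Gprin3 turned when only peaks with a score of at least 100 were used (log2 differences 0.11, -0.42 and -0.45).

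**Figure D3:**
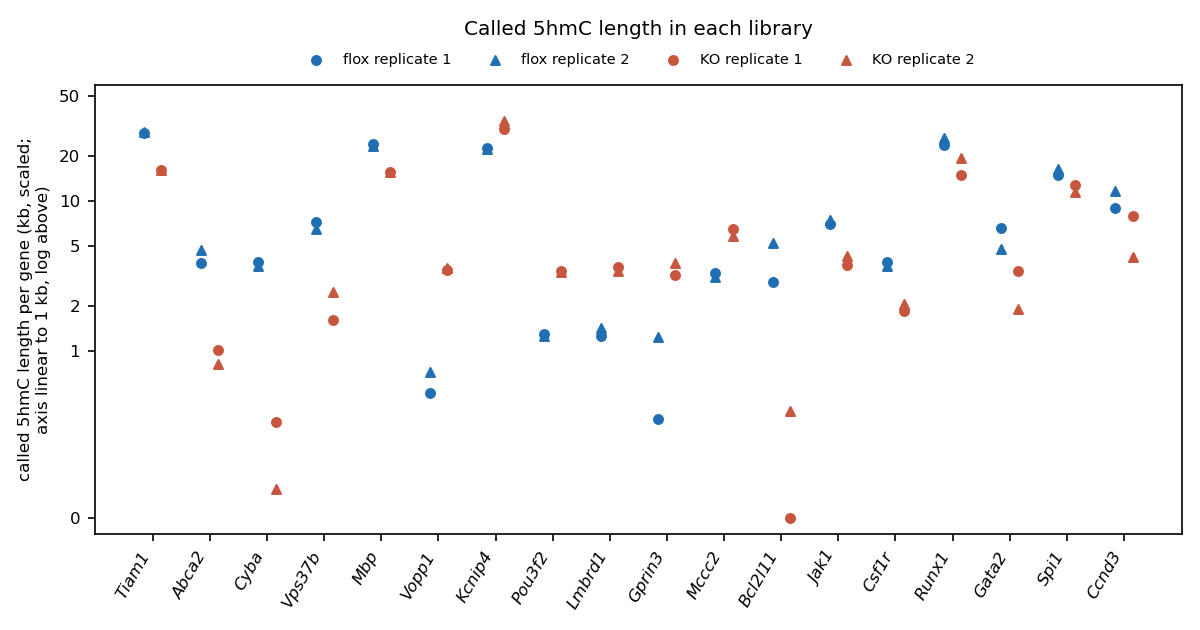
Points give the called 5hmC length in kb (axis linear up to 1 kb and logarithmic above) over each gene and 5 kb on either side, scaled to equal total called length, for flox (blue) and KO (red) replicates 1 (circles) and 2 (triangles). The first 11 genes are among those with the smallest p in each direction, none of which passed the test, and the last 7 were picked, after their values were seen, from the list genes named for an excess of flox-only regions. This choice favours lower values in KO, so the 7 say nothing about list genes as a whole, and others named by the same rule, such as Cux1 and Mitf, are not lower in both KO libraries than in both flox libraries.

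Across the genome, limma found 0 of 14162 protein-coding genes past an adjusted p of 0.05, and the smallest adjusted p was 0.773. At an unadjusted p under 0.05 there were 869 genes, against 708 by chance, of which 609 had less called length in KO and 260 had more (70.1% lower). When the 4 libraries were split by replicate number or crosswise, there were 515 and 539 such genes, of which the lower made up 52.8% and 53.6%. The share depended on the libraries kept, with 47.2% lower without flox replicate 1, 45.3% without flox replicate 2, 84.73% without KO replicate 1 and 81.15% without KO replicate 2. In these data, fits of 1 library against 2 leaned toward lower values in the lone library. Tested alone, a flox library was lower in 65.31% to 70.5% of such genes against a mixed pair and in 52.8% and 54.82% against the KO pair, while a KO library was lower in 75% to 77.45% against a mixed pair and in 81.15% and 84.73% against the flox pair (a comparison chosen after the results were seen). On simulated data of the same size the test found 47% of genes planted with a log2 change of 1 and 74% of those with a change of 3. The simulated genes had a spread smoothed by mean called length, so these shares can overstate what the test finds in the real libraries.

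Genes of cytokine and JAK-STAT signalling, which carries growth factor signals in blood cells, had less called 5hmC in the KO cells as a group. Of 25 measured genes, 21 were lower, with a median log2 difference of -0.30 (camera, preset correlation, adjusted p = 0.00487). With an estimated correlation the call was lost (adjusted p = 0.406). Jak1, a receptor-bound tyrosine kinase (chromosome 4, 101151974 to 101265282), had 7260 bp in flox and 4030 bp in KO (log2 difference -0.78, SE 0.17) and 2 flox-only regions. The cyclin gene Ccnd3 (chromosome 17) had 10317 bp and 6110 bp (-0.76, and -0.34 without KO replicate 2), while Lyn, a Src family kinase gene with 1 KO-only region, differed by 0.11. The 4 genes at an unadjusted p under 0.05 were Jak1, Jak2 (-1.61), the interleukin 3 receptor gene Il3ra (-0.55) and Stat5b (-0.49), and the last 3 were chosen after their values were seen.

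Stem and progenitor cell regulators were the other group with less called 5hmC in KO, with 19 of 25 measured genes lower and a median log2 difference of -0.44 (camera adjusted p = 0.00999). This call, too, was lost (adjusted p = 0.406 with an estimated correlation). Runx1, the transcription factor gene whose product is the AML1 part of AML1-ETO (chromosome 16, 92601466 to 92826074), had 25142 bp in flox and 17223 bp in KO (-0.54, SE 0.15) and 3 flox-only regions. Its difference was -0.36 without KO replicate 1 and turned to 0.11 within 2 kb of gene ends. Gata2, a transcription factor of stem and progenitor cells (chromosome 6, 88193891 to 88207032), had 5678 bp and 2657 bp (-0.996, SE 0.31) and 2 flox-only regions. Mecom, a zinc finger transcription factor gene, stood at 0.29, with 1 KO-only region. Myb (-0.98) and Tal1 (-0.89), also transcription factors of progenitors, were chosen after their values were seen, and Myb turned to 0.37 with only peaks of a score of at least 100. Hoxa9 and Hoxa10 share their peaks and so give 1 value for 2 members. Kit is in both lists and had a difference of -0.55.

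The estimated correlation between genes was -0.0198 in the stem cell list and -0.0314 in the cytokine list, and camera's test with it rests on the 2 residual degrees of freedom of the 4 libraries. No member of either list passed limma's test over all genes, and none passed when adjusted over the list alone. Both calls also ended with the 50000 highest scored peaks of each library (adjusted p = 0.196 for both) and over gene bodies alone (0.201 for cytokine genes and 0.170 for stem cell genes), by number of peaks (0.0820 and 0.337) and within 2 kb of gene ends (0.756 and 0.958, an interval chosen after seeing the data). With only peaks of a score of at least 100 the stem cell call ended (0.268). Without KO replicate 2 they were 0.0644 and 0.0996, without flox replicate 2 0.102 and 0.0754, and without flox replicate 1 the stem cell list stood at 0.211.

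The other 9 lists did not pass (camera adjusted p from 0.781 to 0.976), and none of their members passed over all genes. Among partners and targets of AML1-ETO, 12 of 24 measured genes were lower and 12 higher (median -0.02). Of all 9 lists, 1 member passed when adjusted over the list alone. Tcf12 and Tcf4, genes of E proteins, had 1 KO-only region each and differences of 0.26 and -0.07. Of the leukaemia tumour suppressors, 14 of 23 were lower (median -0.08). In this list Bcl2l11, which encodes the cell death protein BIM (chromosome 2, 128126038 to 128162547), had 4088 bp and 321 bp (-2.55, SE 0.50) with 2 flox-only regions, and Cux1 had 3 flox-only regions with a difference of -0.08. The histone methyltransferase genes Ezh2 and Kmt2c were higher (1.08 and 0.87), each with 1 KO-only region.

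Of the granulocyte and monocyte genes, 14 of 22 were lower (median -0.11). Csf1r, the receptor gene for macrophage colony-stimulating factor (chromosome 18, 61105572 to 61131139), had 3817 bp and 1956 bp (-0.81, SE 0.21) with 2 flox-only regions, and the myeloid transcription factor gene Spi1 had 15625 bp and 12110 bp (-0.36). Cd14, listed at 0 bp in both flox libraries, had 1634 and 575 bp in the KO libraries, and Itgam differed by 0.38. Of the genes of TET and DNMT enzymes and base excision repair, 10 of 15 were lower (median -0.09), and Cxxc5 and Dnmt1 had 1 flox-only region each (-0.47 and -0.20).

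Marker lists of other cell types were balanced between lower and higher genes when all peaks were used. With only peaks of a score of at least 100, neuronal genes passed as higher in KO (median 0.105, camera adjusted p = 0.0447). The lymphoid, erythroid and liver medians then also turned in sign. Lymphoid genes split into 12 lower and 12 higher (median 0.01), with examples in Cd4 (-0.26), Foxo1 (-0.86), Bach2 (-0.01) and Blnk (-0.01). For erythroid, megakaryocyte and mast cell genes the numbers were 10 and 9 (median -0.01). Of these, Ank1 differed by -0.06, Mitf by -0.01, Gata1 by -0.46 and Tfrc by 0.95 (0.26 without flox replicate 2). Neuronal genes had 13 lower and 11 higher (median -0.01), among them the long genes Ptprd (0.12), Rbfox1 (0.06) and Csmd1 (0.12). Liver genes had 8 and 8 (median 0.00), with C3 at -0.56, Cps1 at -0.69 and Alb at 1.499, and Apoa2, with 1 KO-only region, was under the length minimum. Housekeeping genes had 7 lower and 3 higher (median -0.10), with Polr2a at -0.49 (-0.00096 without KO replicate 2) and Reep5 at -0.96. For lymphoid genes the mean (-0.04) had the opposite sign of the median and of camera's direction, and for neuronal genes camera's direction was up although median and mean (-0.01) were below 0. In the erythroid list the median was below 0 while the mean (0.10) and camera's direction were above it.

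Counted as regions, cytokine genes held 9 flox-only regions and 1 KO-only region (Fisher's exact test against all other genes, p = 0.0252, adjusted p = 0.227). Partners and targets of AML1-ETO held 13 and 3 (exact p = 0.0413, adjusted p = 0.227), stem cell regulators 13 and 5 (adjusted p = 0.428), and both granulocyte and monocyte genes and tumour suppressors 8 and 3 (adjusted p = 0.443 each). The TET and DNMT list held 6 and 1 (adjusted p = 0.428), neuronal genes 30 and 33 (adjusted p = 0.513) and lymphoid genes 3 and 6 (adjusted p = 0.499). Erythroid genes held 2 and 2, liver genes 2 and 3 and housekeeping genes 2 and 0 (adjusted p = 1.0, 0.734 and 0.615). No list passed.

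**Figure D4:**
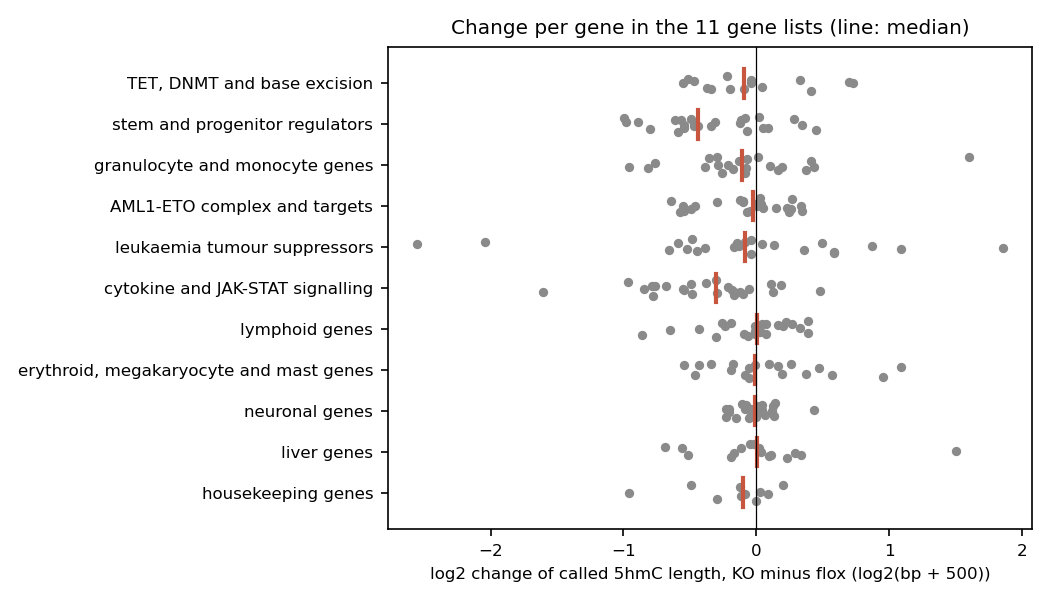
Each point is a gene, placed by its log2 difference of called 5hmC length (KO minus flox, on the log2(bp + 500) scale), in rows for the 11 gene lists, with a red line at each list's median. The medians of the cytokine (-0.30) and stem cell (-0.44) lists lie below 0, and those of the other lists lie between -0.11 and 0.01.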

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

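The intervals of 2 kb around gene ends and the counts by a score of at least 80, 120 or 150 in both libraries of a pair were chosen after seeing the data, as was the comparison of 1 library with mixed pairs. The excess of flox-only over KO-only regions in genes kept its side in all alternatives (odds ratio 1.283 to 1.494) and without each library (1.168 to 1.304), as did regions over 100 kb from genes (0.660 to 0.733, and 0.731 to 0.811). No gene passed under any alternative. In all, 144 of the values that answer a comparison kept their direction and side or, for counts, changed little or not at all. Of the rest, 42 moved, 16 no longer passed and 5 reversed. Among the 144 are the counts of genes that passed, which have no direction and were the same in every alternative. Also among them are camera's results in limma without trend or robust, which equal those with the settings of the report. The tally can therefore overstate how far the results hold. For the other lists and genes named, 937 held and 83 reversed, none of which had passed with the settings of the report. Where no cause is given below, the cause was not tested.

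With a score of at least 100 there were 2598 flox-only and 3145 KO-only regions (ratio 0.826), and with the 50000 highest scored peaks 2667 and 2615. Windows of 500 bp gave 13753 and 12700 (1.083), since a wide region holds several windows. A score of at least 80 in both libraries left 764 and 684 (1.117), 120 left 55 and 33 (1.667), and 150 left 13 and 6 (2.167). Leaving out 1 library, which loosens the demand on that genotype, gave 11283 to 17611 and 12278 to 18189 regions (ratio 0.62 to 1.372). The KO minus flox difference ran from -2085.5 to 3476.5 peaks and from -2.63 to 0.42 Mb without a library in turn, and was 0.59 Mb with a score of at least 100 (exact permutation p = 0.667).

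The share of lower genes among those at an unadjusted p under 0.05 was 73.25% with a mean of at least 2000 bp, 66.45% in limma without trend or robust and 61.24% around gene ends. It ran from 45.26% to 84.73% without a library in turn, below 50% without either flox library and above 80% without either KO library. Fits of 1 library against 2 leaned toward lower values in the lone library, whichever library it was, and the cause of this lean was not tested. Against a pair of 1 flox and 1 KO library, the lone library was lower in 65.31% to 77.45% of such genes over 8 fits, and the lone sample is assumed to vary like the other group.

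The 2 lists that passed had the same direction throughout. With an estimated correlation 0 lists passed, and the medians of -0.4408 (stem cell) and -0.3022 (cytokine) stand as before (adjusted p = 0.406 for both), because that setting leaves the values as they are. It tests them with 2 residual degrees of freedom, and the correlations it estimated were below 0 (-0.0198 and -0.0314). Again 0 lists passed with the 50000 highest scored peaks (-0.2044 and -0.2966), gene bodies alone (-0.2415 and -0.1689), gene ends (-0.0015 and -0.0764) and the number of peaks (-0.2946 and -0.2969). With a score of at least 100 the stem cell list stood at -0.1992 (adjusted p = 0.268). Over these alternatives adjusted p ran from 0.00349 to 0.958 for stem cell genes and from 0.0029 to 0.756 for cytokine genes. Without a library in turn 0 to 2 lists passed, with medians of -0.3668 to -0.2727 (adjusted p 0.0160 to 0.211) and -0.4468 to -0.2491 (0.00935 to 0.102).

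Lists that had not passed turned in sign as follows. With a score of at least 100, medians were 0.105 for neuronal genes, which then passed (adjusted p = 0.0447), -0.1981 for lymphoid, 0.0779 for erythroid and -0.1224 for liver genes. With the 50000 highest scored peaks they were 0.0588, -0.0801, 0.2687 and -0.1511, and 0.0058 for tumour suppressors and 0.0049 for housekeeping genes. Around gene ends neuronal genes stood at 0.0465, lymphoid at -0.0016, liver at -0.5171 and tumour suppressors at 0.415. With a mean of at least 2000 bp they were 0.0001 (neuronal), -0.0382 (lymphoid) and -0.1885 (liver). Lymphoid and liver genes stood at -0.0033 and -0.0082 when not scaled and at -0.0039 each by number of peaks. Erythroid genes stood at 0.0011 by number of peaks, 0.0461 without a filter, 0.0156 and 0.0152 with pseudocounts of 100 and 2000 bp, and 0.0742 without the 10% lowest scored peaks. Liver genes stood at -0.0169 without a filter and -0.0001 with the pseudocount of 2000 bp. Without a library in turn, medians ran from -0.1276 to 0.0454 (erythroid), -0.2802 to 0.0594 (housekeeping), -0.2743 to 0.205 (tumour suppressors), -0.0585 to 0.03 (liver), -0.0152 to 0.0716 (lymphoid) and -0.0291 to 0.0636 (neuronal).

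Of named genes, these turned with a score of at least 100: Abca2 (0.11), Kcnip4 (-0.42), Gprin3 (-0.45), Myb (0.37), Dnmt1 (0.69), Gata1 (0.26), Mitf (0.38), Ank1 (0.1) and Rbfox1 (-0.01). With the 50000 highest scored peaks they were Abca2 (0.13), Kcnip4 (-0.73), Myb (0.39), Dnmt1 (0.22), Gata1 (0.28), Mitf (0.41), Ank1 (0.25), Blnk (0.07) and Rbfox1 (-0.03). Around gene ends Runx1 (0.11), Abca2 (0.13), Myb (0.03), Ank1 (0.16), Cd4 (0.1) and Ptprd (-0.01) turned. Over gene bodies alone Tet2 (0.05), Dnmt1 (0.01), Cd4 (0.07) and Blnk (0.04) did. Without the 10% lowest scored peaks Cux1 (0.12), Ank1 (0.07), Blnk (0.11) and Bach2 (0.03) turned, as did Bach2 by number of peaks (0.07) and Mitf with a pseudocount of 100 bp (0.02). Without a library in turn, 30 of 54 named genes moved by over 1.5 times or crossed 0. Of these, 21 kept their sign: Tet3 (-0.768 to -0.26), Runx1 (-0.729 to -0.356), Gata2 (-1.35 to -0.645), Myb (-1.43 to -0.539), Tal1 (-1.33 to -0.457), Kit (-0.76 to -0.332), Ccnd3 (-1.18 to -0.337), Jak2 (-2.16 to -1.06), Lyn (0.00863 to 0.216), Ezh2 (0.568 to 1.6), Itgam (0.222 to 0.53), Cxxc5 (-0.706 to -0.237), Dnmt1 (-0.379 to -0.0116), Foxo1 (-1.2 to -0.52), Gata1 (-0.794 to -0.132), Tfrc (0.259 to 1.64), Csmd1 (0.0123 to 0.228), Rbfox1 (0.0298 to 0.0993), Alb (0.82 to 2.18), Cps1 (-1.14 to -0.242) and Polr2a (-0.981 to -0.00096). For the other 9, ranges crossed 0, namely for Tet2 (-0.45 to 0.27), Tcf12 (-0.43 to 0.94), Tcf4 (-0.31 to 0.18), Cux1 (-0.18 to 0.02), Mitf (-0.95 to 0.94), Bach2 (-0.15 to 0.14), Blnk (-0.25 to 0.23), Ank1 (-0.13 to 0.02) and Ptprd (-0.03 to 0.27).

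With the replicate block, 0 genes passed in either direction, 71.2% of genes at an unadjusted p under 0.05 were lower (628 against 254), and the same 2 lists passed (adjusted p = 0.00435 for cytokine and 0.00444 for stem cell genes). Deviations of same-numbered libraries did not go together across 14162 genes (Pearson r = 0.0065, Spearman rho = -0.0131, genes not being independent replicates). This does not exclude a culture or preparation shared by libraries of the same number, which the labels do not give. Promoters alone, a start site window of 2 kb and the exons of Tet2 were planned and not run, because strand and exons were not analysed here. Depth was unknown, so a weak peak missing from a list does not show that 5hmC was absent.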

Other observations

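The counts of wide and of high-scored regions and the other splits as a test of the share in genes and of the share of lower genes were chosen after the results were seen. Broad 5hmC regions were more frequent among regions of the flox cells. There were 38 flox-only and 13 KO-only regions of at least 2000 bp (Fisher's exact test on the shares of 0.74% and 0.25%, p = 0.000364), while the 4 pairs of a flox and a KO library had 10 to 18. At a minimum of 1500 bp the numbers were 181 and 137 (exact p = 0.00872), against 88 to 124 in mixed pairs.

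The regions of 1 genotype with a score of at least 150 in both libraries numbered 13 in flox and 6 in KO, against 3 to 8 in mixed pairs. A flox region of this kind lay between Rpn1 and Gata2 (chromosome 6, 88115937 to 88117942), 75.9 kb from Gata2 and 10.6 kb from Rpn1. The interval between these genes is known to hold a distal enhancer of Gata2, and overlap with it was not tested. Others lay in Trp53bp2, the p53-binding protein gene (chromosome 1, 182431574 to 182433063), in Dnajb12 (chromosome 10, 59894962 to 59896532), in Mvd (chromosome 8, 122436087 to 122437734), in the overlapping genes Dock6 and Angptl8 (chromosome 9, 21834877 to 21836820), in Fryl (chromosome 5, 73133043 to 73133703), in Trak1 (chromosome 9, 121382442 to 121383400), in Rufy4 (chromosome 1, 74147455 to 74148570) and in Cplane1 (chromosome 15, 8255983 to 8256521), and the other 4 of the 13 lay between genes. KO regions of this kind lay in Gse1 (chromosome 8, 120320325 to 120320782) and Rorb (chromosome 19, 19099819 to 19100275), and the other 4 between genes.

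Flox-only regions lay in genes 7.48 percentage points more often than KO-only regions. The other splits of the 4 libraries gave differences of at most 2.09 points in size, which argues against spread between libraries of this kind, although 3 splits are too few to exclude chance. Within strata of peak score and width the odds ratio was 1.314 (95% interval 1.213 to 1.422), and within strata of gene density 1.247 (1.15 to 1.353), so neither stronger peaks nor a gradient with gene density accounts for the whole. Base composition was not analysed here and stays open, as does a difference in depth between the libraries, because depth was unknown. Median peak score was 94.17 and 93.41 in flox and 94.46 and 96.56 in KO replicates 1 and 2. Flox-only regions between genes also had more genes around them (mean 8.43 against 7.33 genes in 1 Mb, permutation p = 1e-05, the smallest that 100000 permutations give). Mixed pairs of libraries stood at 36.76% to 38.97% in genes, close to the KO-only share of 36.3% and below the flox-only share of 43.8%. The Tet2 genotype, with the drug that KO cultures alone were given, stays open as an explanation that was not tested.

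Cytokine and stem cell genes had lower medians of called length in KO, with camera calls at the preset correlation that were lost with an estimated one (adjusted p = 0.406 for both with an estimated correlation), and no member passed. That test has 2 residual degrees of freedom, and the correlations themselves were below 0 (-0.0198 for stem cell and -0.0314 for cytokine genes). Among 10000 random lists matched on called length, gene length and gene density, the stem cell median lay below all and the cytokine median at percentile 0.24, which argues against these properties as the cause. In the other splits of the libraries the smallest adjusted camera p of either list was 0.7319. GC content and the Tet2 genotype, with the drug that KO cultures alone were given, stay open and were not tested. Depth was unknown, so a difference in depth between the libraries stays open as well.

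Genes at an unadjusted p under 0.05 were lower in KO in 70.08% of cases, and in the other splits in at most 53.62%. The share falls below 50% without either flox library, and fits of 1 library against 2 leaned toward lower values in the lone library. Whether that lean accounts for the fall was not tested. A difference in depth between the libraries stays open because depth was unknown. The Tet2 genotype, with the drug that KO cultures alone were given, stays open too and was not tested as an explanation.

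Gene families defined by a shared start of the symbol were tested for moving together. Of 100 families with 15 or more measured genes, 0 passed camera at an adjusted p of 0.05. An unadjusted p under 0.05 was found for 5, which is the number expected by chance over 100 tests. These 5 were Zbtb and Map (lower in KO) and Cdh, Ube and Dnah (higher), with an adjusted p of 0.671 each, and they were named after their values were seen.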
